A study of Mus musculus with 5 samples.

How the data were processed

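The series holds 5 single-cell RNA-seq libraries of mouse otocyst cells, 1 library per group. Per the labels' protocols, dissected inner ear tissue was digested with papain for a time that depended on age, cells bound by an EpCAM antibody were sorted, and libraries were made with the 10x Genomics 3' v3.1 chemistry, which counts unique molecular identifiers (UMIs). EpCAM is a surface protein of epithelial cells, so the sort sets which classes are seen and their shares. 4 libraries came from outbred ICR embryos at embryonic days (E) 9.5, 10.5, 11.5 and 12.5. The fifth came at E10.5 from a cross of Pax2-Cre males with NICD-GFP females. NICD, the Notch intracellular domain, is the fragment of a Notch receptor that signals in the nucleus, and Pax2-Cre is active in the otic placode. The embryos were picked by their phenotype: the otic placode had not invaginated and the neural tube had not closed.

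The deposited values are raw UMI counts per gene and barcode, not normalized, written by Cell Ranger 7.1.0 per the file headers. The genome was mm10, per the submitters' processing notes. The annotation release, and whether intronic reads were counted, are not given in the sources used here. The matrices list every barcode with a count and not only cells: 1982656, 2058754, 2461788 and 2019583 barcodes for ICR E9.5 to E12.5 and 2348520 for NICD. They sum to 191158687, 195737616, 220264297, 158410922 and 222447957 UMIs. The 4 ICR matrices share an annotation of 32285 features, and the NICD matrix has 21685. All levels are therefore CPM, UMIs of a gene scaled to the same total in every library, over the 21321 genes that both annotations hold.

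A barcode was kept as a cell when its UMIs reached 10% of the 99th percentile of the 5000 largest barcodes of its library, it had at least 1000 genes and at most 10% of its UMIs were mitochondrial. The UMI minimum came to 5251, 3992, 7603, 4572 and 4415, in the order ICR E9.5 to E12.5 and NICD. Doublets were scored with Scrublet as implemented in scanpy. Its automatic threshold marked 5.36% of the ICR E9.5 cells and 4.72% of the ICR E12.5 cells. It marked 0, 4 and 0 cells in ICR E10.5, ICR E11.5 and NICD, where the highest scores were left out in its place at 0.8% per 1000 cells, which removed 1610, 1253 and 2455 barcodes. This left 9074, 12575, 11264, 11456 and 15064 cells with a median of 16725, 10790, 11732, 10453 and 9857 UMIs.

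Log-normalized counts of the 5 libraries were clustered together without batch integration: 3000 variable genes, 30 principal components, 15 neighbours and Leiden at resolution 1, with seed 0. Genes of the 4 Notch lists and the 2 cell cycle phase lists, mitochondrial, ribosomal protein, haemoglobin, X-inactivation and Y-linked genes were kept out of the variable genes. This gave 34 clusters. They were named from 12 marker sets. The markers were fixed before the data were examined, together with the filters, the lists, the comparisons and 16 of the alternative choices, and the scoring rule was set after the files were seen. A marker counted as on at 20 CPM or more and at a log2 of at least 1 above the lower quartile of the clusters. A name needed 3 markers on, a score (the mean over the set of the log2 above that quartile, with 10 CPM added) of at least 1, and a median mitochondrial share of at least 0.5%. The minimum score was first 0.8 and was raised after it had named 1455 NICD cells neuroblast-like with each library clustered alone. A cluster whose leading genes held more markers of another class, or of hair cells, than of its own stayed unnamed or took the next class, as would a cluster of shallow cells with none of its markers among the leading genes. 8 clusters stayed unnamed.

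UMIs were summed per library and class. A ratio of CPM has an exact conditional binomial 95% interval, a sum an exact Poisson interval and a share an exact binomial (Clopper-Pearson) interval. The limit given beside a count of 0 is 3 counts over the total, and all of them cover counting error only. Cells are not replicates and every group has 1 library, so no test was run and no p-value is given. A class was compared where both libraries held at least 50 of its cells. Genes were named by a fixed rule of size: for each of 29 gene lists, the members of largest log2 ratio, and over all genes of at least 50 CPM in 1 of the libraries compared, the 10 highest and the 10 lowest by log2 ratio after 10 CPM was added to both. Genes named for the stage comparison had to go one way over all 4 ICR libraries, and those named for NICD had to lie at least 1.5-fold outside the range of the 4. Mitochondrial, ribosomal protein, haemoglobin, X-inactivation and Y-linked genes and gene models without a name were left out, and some genes that the rule names are not reported here. List members counted as measured at 20 CPM or more in 1 of the libraries, and as higher or lower at 2-fold after the 10 CPM were added. A fold in the text is the plain ratio of CPM. The median log2 ratio of a list is given with its percentile among 10000 random lists of the same size, matched in 20 bins of mean expression, as a description of these libraries. Some list members are also naming markers, among them Oc90, Otol1, Lmx1a and Dlx5 for otic epithelium and Tubb3 and Gap43 for neuroblasts. Lists that hold them are not independent of the class names.

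To compare shares of cells with a UMI across depths, each cell was thinned to 4500 UMIs. Shallower cells were left out: 0, 828, 0, 37 and 101 in the order given above. A G2/M share is the share of thinned cells with at least 5 summed UMIs of the G2/M list, a range of a score and not a cell type. Barcodes under 100 UMIs served as empty droplets. Gene spans, exons and coordinates were taken from GENCODE M21 on GRCm38, the assembly that mm10 names.

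The interval, size rule and list steps were tested on simulated counts with 200 changed genes. For the stage comparison in otic epithelium-like cells (3639 genes) 94.9% of the intervals held the true ratio, and for the NICD comparison (3766 genes) 95.1% did. In both, 100% of the genes changed by a log2 of 1.5 (100 genes) and of 2 (100 genes) passed the 2-fold rule, 0 unchanged genes did, and all 20 genes named were changed ones. A raised list reached percentile 100, and 3 and 4 of 100 unchanged lists fell outside the middle 95%. The simulated counts held Poisson error only, with no difference between libraries or in naming, so coverage and recovery were bound to be high. Genes were taken there by ratio alone, without the stage order and range rules. The simulation therefore says nothing about variation between libraries.

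Alternatives covered cell calling, the mitochondrial limit, doublets, resolution, clustering of each library alone, variable genes, scaling, cell weights, background RNA, depth, the annotation in the CPM total, the prior, the gene filter, the stages compared and the reference library. A further 5 were chosen after seeing the data: barcodes of little mitochondrial RNA left out, clusters named irrespective of that RNA, cluster 14 taken as otic, genes that share exons with a feature of 1 annotation left out, and a naming score of 0.8. Scaling by median-of-ratios moved the median of all genes by a log2 of −0.29 in the stage comparison of otic epithelium-like cells and by −0.10 in that of neuroblast-like cells. For NICD over ICR the shift was 0.12 in pharyngeal endoderm-like, −0.08 in neural tube-like, 0.06 in otic epithelium-like and −0.06 in all cells. Values in all these comparisons are therefore relative. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.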

Results

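The otocyst, the epithelial vesicle that forms the inner ear, was profiled cell by cell in 5 libraries of EpCAM-sorted mouse cells. 4 were wild type (ICR) at E9.5, E10.5, E11.5 and E12.5, and 1 was from E10.5 embryos of the Pax2-Cre by NICD-GFP cross. The series title names the question: how gene expression, and Notch signalling in particular, runs over early inner ear development. The 9074, 12575, 11264, 11456 and 15064 cells kept (ICR by stage, then NICD) held a median of 4504, 3636, 4122, 3701 and 3555 genes. There were no replicates, so stage or genotype cannot be told apart from the library, and every interval below covers counting error only.

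Otic epithelium-like cells were the largest class in every ICR library. They made up 39.8% of ICR E9.5 cells (95% interval 38.8 to 40.8), 42.2% at E10.5, 82.3% at E11.5 and 65.0% at E12.5. Otic neuroblast and neuron-like cells, which form the cochleovestibular ganglion, made up 7.88% (7.33 to 8.45), 11.2% (10.6 to 11.7), 7.55% (7.07 to 8.05) and 1.40% (1.19 to 1.63). In the NICD library they were 4 of 15064 cells, or 0.0266% (0.0072 to 0.068), and otic epithelium-like cells were 25.5% (24.8 to 26.2). Pharyngeal endoderm-like cells were 30.0% at E9.5 and 5.03% at E10.5, 1.5% and 3.28% at the later stages and 1.04% in NICD. Most of those at E9.5 were cluster 6, whose name was its class of second highest score, with 4 markers on. Clusters 24 (pharyngeal endoderm), 28 (neuroblast) and 29 (neural tube) also bear their class of second highest score, so these names are less secure. Surface ectoderm-like cells were 6.85%, 3.75%, 3.82% and 7.39% over the ICR stages and 0.113% in NICD. Epibranchial neuroblast-like cells were 11.9% at E9.5, 5.02% at E10.5 and 0.213% at E11.5, were 0 of 11456 at E12.5, which allows a share of up to 0.0262%, and were 0.073% in NICD. Neural tube-like, mesenchyme-like, macrophage-like and erythroid-like cells each made up under 2% of every library, and no cluster was named neural crest, endothelium or megakaryocyte.

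Some of these shares depended on the setting. Otic epithelium-like cells were 0.0457% of the NICD library with doublets kept and 6.78% with a minimum of 2000 UMIs. At Leiden resolution 0.5, pharyngeal endoderm-like and surface ectoderm-like cells were 0.0992% and 36.96% at E9.5 and 1.77% and 9.88% at E10.5, and with doublets kept they were 0.136% and 35.5% at E9.5. With each library clustered alone, neuroblast-like cells were 14.82% at E9.5 and 10.47% at E10.5, the reverse order, and epibranchial neuroblast-like cells 4.97% and 8.26%, also the reverse. In that setting pharyngeal endoderm-like cells were 13.0% at E9.5, and surface ectoderm-like cells were 3.95% in NICD. With a naming score of 0.8 as well, chosen after seeing the data, neuroblast-like cells were 9.66%, mesenchyme-like cells 12.03% and pharyngeal endoderm-like cells 2.90% in NICD. Otic epithelium-like cells were 70.1% and pharyngeal endoderm-like cells 7.90% at E10.5 with clusters named irrespective of their mitochondrial share, also chosen after seeing the data. With at most 5% mitochondrial UMIs, endothelium-like cells were named and were 2.95% at E12.5.

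**Figure D1:**
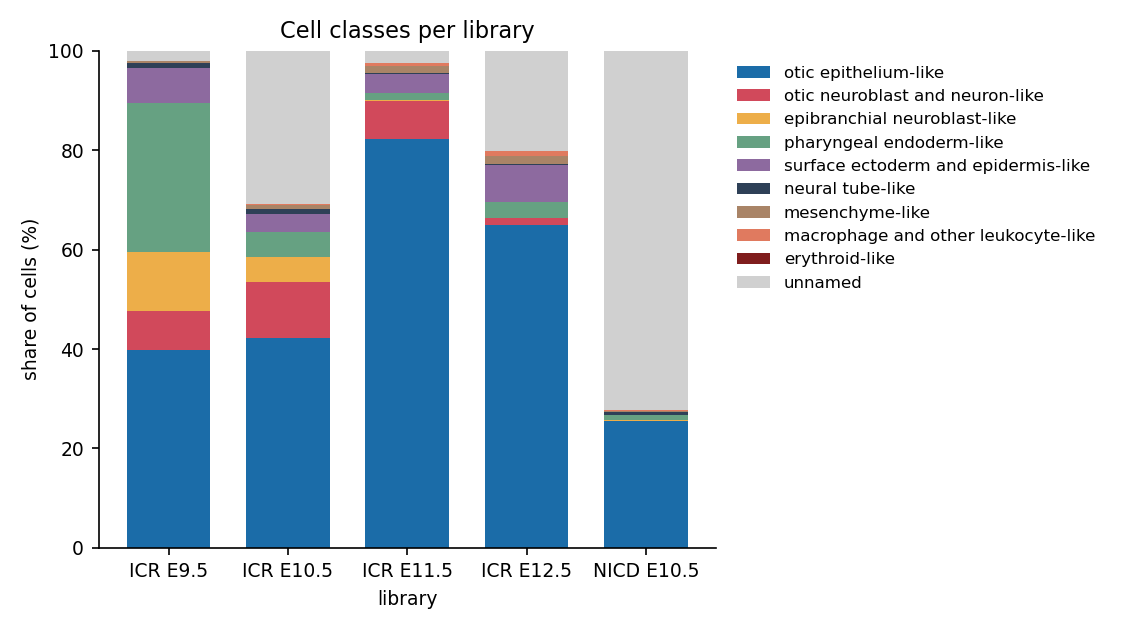
Stacked bars of the share of cells in percent that each class took in each of the 5 libraries, with unnamed clusters in grey. Otic epithelium-like cells took 39.8% at E9.5 and 82.3% at E11.5, and unnamed cells took 72.2% of the NICD library.

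The unnamed share differed widely. It was 1.99%, 30.8%, 2.37% and 20.2% over the ICR stages and 72.2% in NICD. At E10.5 most of it was cluster 1 (27.9% of the library; 1.84% at E9.5, 0.719% at E11.5, 0.803% at E12.5, 0.126% in NICD). Its cells had otic markers on but a median mitochondrial share of 0.066%, below the minimum set after the files were seen. Cluster 27 (2.88% at E10.5, 0.154% at E9.5, 0.009%, 0.044% and 0.033% elsewhere) had 2 markers on for its class of highest score, where 3 were needed, and a median mitochondrial share of 0.070%. At E12.5 it was mostly cluster 14 (14.8% there, 1.59% at E11.5, and no cell in the other libraries), in which the mesenchyme markers Dcn and Lum were among the leading genes beside the otic matrix gene Tecta. Otic epithelium was the class of highest score of cluster 14, with 9 markers on. In NICD the unnamed share was clusters 0, 5 and 10 (33.8%, 21.9% and 16.3%), almost without cells of other libraries. Ptges, which makes prostaglandin E2, the Wnt modulator Sfrp2, the Notch target Hes5 and the homeobox gene Uncx led clusters 0 and 10, and Stmn2, Il7 and Cacna2d3 led cluster 5. The otic epithelium-like class itself was held by different clusters: cluster 3, with 3578 cells, at E9.5, clusters 4, 19, 20 and 22 at E10.5, clusters 9, 13 and 18 and others at E12.5, and cluster 2, with 3838 cells, in NICD. A cluster mostly of 1 library can be that library and not a type.

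The first comparison set otic epithelium at E12.5 against E9.5. Tectorial and otolithic membrane genes, and the single genes Sparc, Nfia and Nfib, were far higher at E12.5, and Crabp1, Lin28a and Sall4 were far lower. Oc90, otoconin-90 of the otoconial matrix (ENSMUSG00000015001, chromosome 15, 65876053 to 65912397, minus strand, GRCm38), stood at 37.8, 385, 1031 and 2544 CPM over the 4 stages, 67.3-fold higher at E12.5 (64.8 to 70.1). The collagen-binding glycoprotein gene Sparc (ENSMUSG00000018593, chromosome 11, 55394500 to 55423183) went from 16.0 to 825 CPM, 51.6-fold (48.6 to 54.9). Crabp1, which binds retinoic acid (ENSMUSG00000032291, chromosome 9, 54764748 to 54773110), went the other way, from 394 over 80.0 and 18.6 to 5.06 CPM, 77.8-fold lower (70.8 to 85.8). These sums rest on 85379014 UMIs from 7443 cells at E12.5 and 67264875 UMIs from 3612 cells at E9.5.

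Among the other genes of largest ratio, the transcription factors Nfia and Nfib were 47.2-fold (44.5 to 50.2) and 50.5-fold (47.1 to 54.1) higher. Clusterin (Clu) was 239-fold higher (192 to 302), the adhesion molecule Ntm 60.4-fold (54.8 to 66.7) and Frmpd4 141-fold (116 to 173). Il1rapl1 was 522-fold higher (366 to 774) from 30 UMIs at E9.5, and the proteoglycan gene Lum 1206-fold (731 to 2155) from 15 UMIs. Lum, a mesenchyme marker that leads the unnamed cluster 14, did not exceed its level in empty droplets at E12.5 (269 against 278 CPM). Oc90, Clu, Il1rapl1, Nfia, Ntm and Frmpd4 lead clusters of the later stages, so their order partly repeats how those clusters were drawn. Lower at E12.5 were Lin28a, an RNA-binding protein that blocks let-7 maturation (186-fold, 133 to 269), Trim71, a regulator of developmental timing (6.56-fold, 6.13 to 7.02), the progenitor transcription factor Sall4 (13.1-fold, 11.8 to 14.6), Rasl11a (11.7-fold, 10.8 to 12.7), metallothionein 1 (Mt1, 10.0-fold, 9.16 to 11.02), Mylk (7.64-fold, 7.12 to 8.19), the carbonic anhydrase gene Car14 (5.05-fold, 4.82 to 5.30) and Prtg (4.95-fold, 4.82 to 5.09). Car4, another carbonic anhydrase, had 1 UMI at E12.5 and a ratio of 9041 (1622 to 357158). Car4, Rasl11a, Lin28a and Crabp1 lead cluster 3, which is the E9.5 class.

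**Figure D2:**
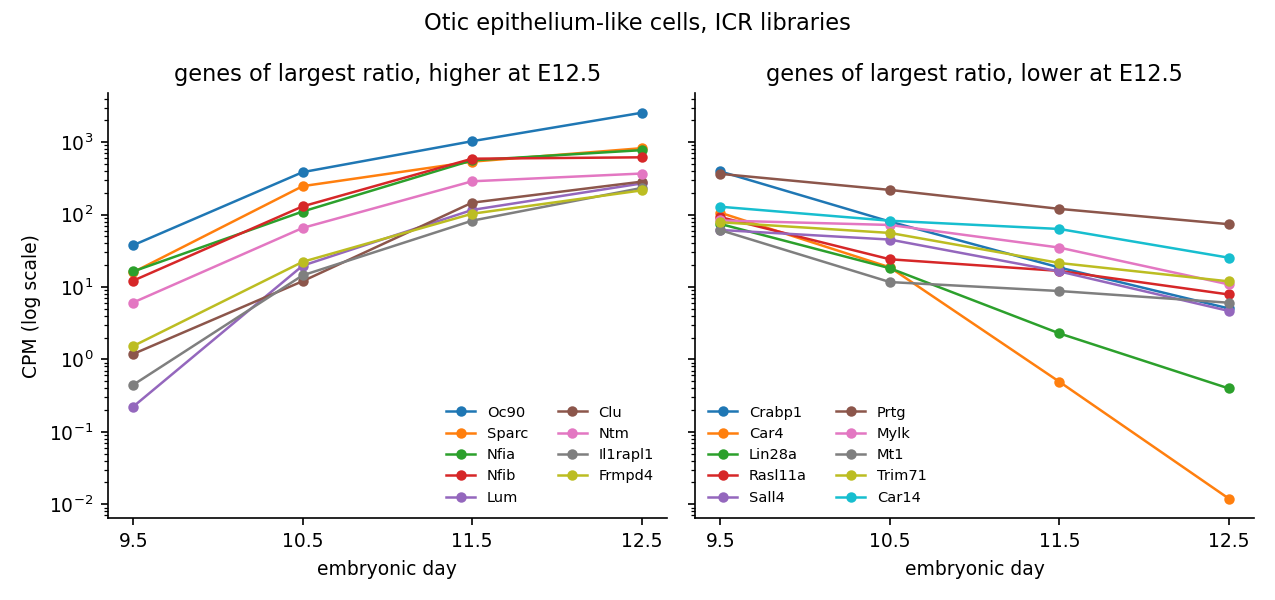
CPM on a log scale against embryonic day in otic epithelium-like cells of the 4 ICR libraries, 1 line per gene, for genes of largest ratio in each direction. Oc90 runs from 37.8 to 2544 CPM and Car4 from 106 to 0.012 CPM.

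All 5 measured tectorial and otolithic membrane genes were at least 2-fold higher (median log2 3.63, percentile 100). Beside Oc90 these included Otol1, an otoconial collagen-like protein (173-fold, 133 to 231), the otogelins Otogl (48.6-fold, 42.4 to 55.9) and Otog (5.35-fold, 4.91 to 5.83), and Tecta (16.3-fold, 13.3 to 20.2). BMP response genes were higher in 5 of 9 (median 1.02, percentile 100), with Smad7 4.38-fold and Id2 2.40-fold higher. Prosensory genes were higher in 4 of 12 and lower in 1 (0.49, percentile 98.6): Isl1, a LIM homeodomain factor, went from 6.17 to 221 CPM, 35.8-fold higher (32.5 to 39.6), while the progenitor factor Sox2 was at 136, 116, 105 and 116 CPM. Isl1, Btg2 (8.31-fold) and Gadd45g (4.86-fold) made up the 3 higher of 4 measured otic neurogenesis genes (1.74, percentile 99.98). Both measured neuronal differentiation genes had a median of −0.83 (percentile 1.46). Otic placode and vesicle regulators were split, 4 higher and 2 lower of 15 (0.40, percentile 94.9): Eya4 was 8.26-fold and Gata2 22.5-fold higher, and the early placode factor Pax8 103-fold lower (75.5 to 143). Regional identity genes were also split, 4 higher and 1 lower of 11 (0.31, percentile 64.2), with Otx2 162-fold higher (110 to 251) and Gbx2 19.5-fold lower (16.7 to 22.9). For E11.5 over E10.5 the medians turned to −0.05 for BMP response, −0.05 for prosensory and −0.35 for regional identity genes, and with no minimum CPM that of otic neurogenesis to −0.04.

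Genes of retinoic acid metabolism and response went both ways, 2 higher and 2 lower of 5 (median −0.64, percentile 1.36): the synthesis enzyme Aldh1a3 was 35.2-fold higher (31.2 to 39.9) and the binding protein Crabp2 2.18-fold lower. Hypoxia and glycolysis genes had a median of −0.67 (percentile 0.06; 3 lower and 1 higher of 9), with lactate dehydrogenase (Ldha) at 1691 CPM at E9.5 and 487 at E12.5. Cholesterol synthesis genes had a median of −0.52 (percentile 0.01; 1 lower of 11), and midbrain and hindbrain patterning genes −0.69 (percentile 0.13; 4 measured). Epithelial junction and keratin genes had a median of 0.45 (percentile 98.6; 1 higher of 13, Cldn3, 3.26-fold), delamination genes 0.85 (percentile 98.4; 2 of 4 higher, with Vim 3.89-fold), Wnt response genes 0.45 (percentile 74.1; Lgr5 3.24-fold higher, Sp5 2.74-fold lower), FGF response genes 0.37 (percentile 87.6; none of 9 past 2-fold) and p53 response genes 0.42 (percentile 79.6). Fewer than 3 members were measured for the hair cell (0.14), interferon (1.42), ion channel (1.18) and Hedgehog (0.64) lists, and no Hox gene was. Immediate early genes, which respond to dissociation, were higher in 5 of 6 (1.84, percentile 99.99), with Fos 55.5-fold and Egr1 21.4-fold higher, and the digestion time depended on age. With no minimum CPM the median of retinoic acid genes turned to 0.35 and that of Wnt response genes was 0.00, and the Wnt median was −0.25 for E11.5 over E10.5.

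In the E12.5 library, macrophage-like cells held the genes that were higher at E12.5 at a median of 74.3% of their otic level, and these same cells had Epcam at 482 CPM against 1085 in otic epithelium-like cells. Empty droplets held the higher genes at a median of 61.9% of the otic level. Clu stood at 285 CPM in otic epithelium-like cells, 257 in macrophage-like cells and 296 in empty droplets, and Lum at 269, 141 and 278. In the same order, Frmpd4 stood at 216, 188 and 92.7 CPM, Nfia at 775, 480 and 368, and Nfib at 618, 384 and 313. Ntm was at 369, 210 and 170 CPM, Il1rapl1 at 233, 121 and 72.3, Sparc at 825, 412 and 515, and Oc90 at 2544, 1178 and 1740. The higher genes were also long: their median span was 176097 bases, against 31161 for all genes measured.

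Of the cell cycle lists, the S phase list had a median log2 of −0.88 at E12.5 over E9.5 (percentile 0; 8 lower of 20), with the ribonucleotide reductase subunit Rrm2 3.32-fold and the replication licensing gene Mcm5 2.47-fold lower. The G2/M list had a median of −0.68 (percentile 0; 3 lower of 22), with Plk1 2.46-fold lower and the median at 0.00 for E11.5 over E10.5, and cell cycle exit genes 0.91 (percentile 99.9), with Btg1 5.37-fold higher. Summed G2/M genes stood at 3891, 3019, 3105 and 2408 CPM. Of otic epithelium-like cells thinned to equal depth, 91.6% (90.6 to 92.4), 60.7% (59.4 to 62.1), 53.6% (52.6 to 54.6) and 31.9% (30.8 to 32.9) had at least 5 G2/M UMIs, and 98.8%, 77.6%, 66% and 40.1% without thinning. Between 4.07% and 9.53% of the thinned cells of each ICR library had 4 or 5 such UMIs.

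For Notch signalling over the stages, the measured target genes did not go together in otic epithelium-like cells. Hey1 (ENSMUSG00000040289, chromosome 3, 8663359 to 8667256) stood at 26.4, 44.2, 61.3 and 83.9 CPM, 3.18-fold higher at E12.5 (3.02 to 3.35), and Hey2 was 2.49-fold higher (2.28 to 2.74). Hes1 was highest at E9.5 (66.3, 39.1, 34.8 and 48.9 CPM; ratio 0.738, 0.707 to 0.770), and the feedback inhibitor Nrarp was nearly level (1.06, 0.998 to 1.13). The median of these 4 was 0.42 (percentile 67.8; 1 higher), and −0.01 for E11.5 over E10.5. The receptors Notch1, Notch2 and Notch3 were 1.61-fold, 1.63-fold and 1.65-fold higher (median 0.58, percentile 89.8). Of the ligands, Jag1 was at 95.4 CPM at E9.5 and 68.8 at E12.5 (0.722, 0.697 to 0.748), and Dlk1 was 6.78-fold higher (6.08 to 7.58). The list median was 0.59 (percentile 57.5). Dlk1 also leads the unnamed cluster 26, with 467 cells at E12.5 and 0 at E9.5, and its level in empty droplets is not given here. Unnamed cluster 14, with 1693 cells at E12.5, lies outside this class, although otic epithelium was its class of highest score. The Jag1 and Hey1 levels of cluster 14 are given below. Among modifiers and effectors (2 higher and 1 lower of 11, median 0.70, percentile 99.6), the co-activator Maml2 was 3.80-fold and the Notch antagonist Numb 2.40-fold higher. Lfng, a glycosyltransferase that modifies Notch receptors (ENSMUSG00000029570, chromosome 5, 140607320 to 140615545), was 8.53-fold lower (7.72 to 9.44), from 44.9 over 38.1 and 11.8 to 5.26 CPM. In cluster 17, with 444 cells at E10.5 and 502 at E12.5, Lfng was 199 CPM (188 to 212) at E10.5 and 14.97 (11.9 to 18.6) at E12.5, while Hey1 was 97.9 (89.7 to 107) and 184 (172 to 195).

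Neuroblast-like cells, 715 at E9.5 and 160 at E12.5 and mostly of cluster 7 in both, had Nfia and Nfib higher at E12.5 as well. Nfib was 92.9-fold (69.9 to 126) and Nfia 29.4-fold (26.0 to 33.4) higher at E12.5. The growth factor gene Tgfb2 was 33.9-fold higher (29.2 to 39.4), Crym, which binds thyroid hormone, 37.5-fold (30.1 to 47.2), Nkain2 29.5-fold (24.1 to 36.5), Fgf13 22.1-fold (17.8 to 27.7) and Tnik 26.6-fold (20.7 to 34.7). Lower were Igfbp5 (12.1-fold, 10.2 to 14.4), the adhesion molecule Cadm1 (2172 to 337 CPM, 6.45-fold, 6.002 to 6.93), Crabp1 (59.6-fold, 23.2 to 219), Prtg (9.30-fold, 7.24 to 12.2), Hs3st1 (10.7-fold, 7.60 to 15.6), Phlda1 (6.27-fold, 5.49 to 7.19) and Lfng (13.5-fold, 8.01 to 24.8). Oc90 (156-fold, 99.01 to 261), Sparc (29.6-fold, 22.5 to 39.6) and Otol1 (660-fold, 181 to 5478, from 2 UMIs) were also higher here. In the E12.5 library Oc90 stood at 252 CPM in these cells, below its 1740 CPM in empty droplets and 1178 in macrophage-like cells, Sparc at 151 against 515 and 412, and Otol1 at 112 against 117 and 59.5. Nfib was at 395 CPM against 313 and 384, and Nfia at 746 against 368 and 480. Nkain2 was at 279 CPM against 106 and 163, Fgf13 at 194 against 58.0 and 108, and Tnik at 165 against 59.5 and 106. Tgfb2 was at 596 CPM against 267 and 251, and Crym at 290 against 134 and 44.8.

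Neuronal differentiation genes were lower in neuroblast-like cells at E12.5 in 3 of 8 (median −0.79, percentile 0): the neuronal tubulin Tubb3 went from 822 to 227 CPM, 3.62-fold lower (3.32 to 3.96), Elavl2 was 4.37-fold and Gap43 2.89-fold lower. With each library clustered alone 11 of 12 were lower, at a median of −2.49. Cells were sorted for EpCAM, so these values describe only the neuroblast-like cells that the sort kept at each stage. Otic neurogenesis genes were lower in 3 and higher in 1 of 13 (−0.35, percentile 0.1), with Pou4f1 4.36-fold lower and Isl1 2.34-fold higher, while the proneural factor Neurod1 was nearly level (0.990, 0.947 to 1.03). The Notch ligands Dll3 and Dll1 were 11.3-fold (6.54 to 21.3) and 3.00-fold (2.12 to 4.38) lower, and Dner, Dlk1 and Jag1 129-fold (49.0 to 484), 7.87-fold (6.07 to 10.3) and 2.03-fold (1.53 to 2.66) higher (median 0.71, percentile 98.96, which turned negative in 6 of the settings tried). Dlk1 leads the unnamed cluster 26 of the E12.5 library, and its level in empty droplets is not given here either. Notch1 was at a ratio of 0.499 (0.424 to 0.584) and the target Hey1 was 5.35-fold higher (3.99 to 7.18). Hypoxia and glycolysis genes were lower in 4 of 7 (−1.07, percentile 0), with Eno1 4.65-fold lower, the G2/M list had a median of −0.24 (percentile 0.07; 0.36 with each library clustered alone) and the S phase list −0.01 (percentile 34.9).

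The second comparison set the NICD library against ICR at E10.5. In otic epithelium-like cells of the NICD library the Notch target genes, Jag1, and genes of hypoxia and glycolysis were far higher than in ICR E10.5, and Oc90, Tbx1 and other regional genes of the otocyst were far lower. Hes1 (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796) stood at 350 against 39.1 CPM, 8.93-fold higher (8.58 to 9.30), Hey1 at 301 against 44.2, 6.81-fold (6.55 to 7.08), and Hes5 (ENSMUSG00000048001, chromosome 4, 154960923 to 154962371) at 62.8 against 1.29, 48.7-fold (39.6 to 60.5). Tbx1, a T-box factor of otic and pharyngeal development (ENSMUSG00000009097, chromosome 16, 18580979 to 18590671), stood at 2.47 against 108 CPM, 43.8-fold lower (36.4 to 53.2), and Oc90 at 3.79 against 385, 102-fold lower (87.6 to 119). The sums rest on 45680514 UMIs from 3846 NICD cells and 72045669 UMIs from 5311 ICR cells.

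Of the 6 measured Notch targets 5 were at least 2-fold higher (median log2 2.02, percentile 100). Heyl was 7.24-fold (6.39 to 8.22), Nrarp 2.69-fold (2.56 to 2.83) and Hey2 2.60-fold (2.37 to 2.86) higher. All 6 also lay above each of the 4 ICR libraries. The ligand Jag1 (ENSMUSG00000027276, chromosome 2, 137081456 to 137116644) was 4.74-fold higher (4.60 to 4.89), at 361 against 76.2 CPM, and Dlk1 3.41-fold (list median 1.58, percentile 99.2). Lfng was 3.94-fold higher (3.77 to 4.12), the only 1 of 10 measured modifiers past 2-fold (median 0.00, percentile 61.0). The receptor Notch1 was 2.03-fold higher (1.95 to 2.12), Notch2 1.27-fold, and Notch3 was at 0.935 (list median 0.27, percentile 86.0). NICD is itself a fragment of a Notch receptor, and whether transgene transcripts were counted as receptor UMIs was not examined.

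**Figure D3:**
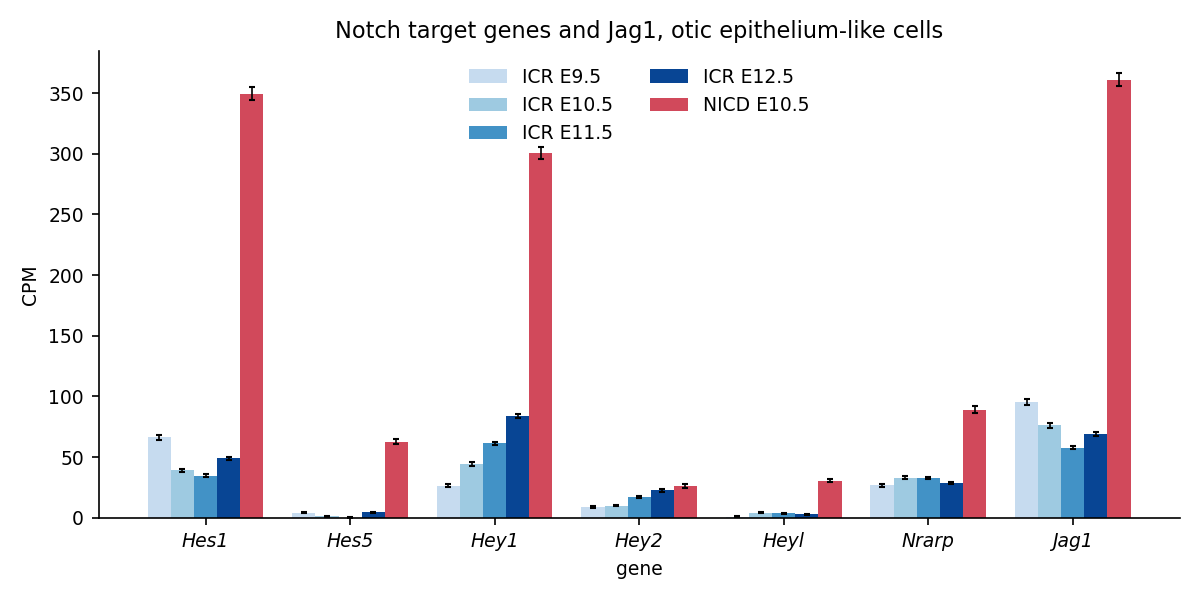
Bars of CPM from 0 in otic epithelium-like cells for 6 Notch target genes and the ligand Jag1 in the 5 libraries, with exact Poisson 95% intervals. The NICD bars of Hes1, Hey1 and Jag1 reach 350, 301 and 361 CPM, against at most 66.3, 83.9 and 95.4 in the ICR libraries.

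At equal depth, 63.3% of NICD otic epithelium-like cells (median 10719 UMIs) had a Hes1 UMI, against 14.1% of ICR E10.5 cells (13065 UMIs) and 22.4% of the 49 NICD macrophage-like cells (12366 UMIs). Unthinned, these were 80.8%, 31.4% and 38.8%. For Hey1 the thinned shares were 67.4%, 17.9% and 4.08% (unthinned 88.1%, 37.5% and 24.5%), for Jag1 74.6%, 25.1% and 8.16% (92.9%, 48.2% and 12.2%), for Nrarp 29.5%, 13.9% and 6.12% (54.1%, 32.9% and 14.3%), and for Hes5 16.2%, 0.554% and 2.04% (27.2%, 1.54% and 6.12%). Oc90 was found in 1.44% of NICD and 39.7% of ICR otic epithelium-like cells and in 0 of the NICD macrophage-like cells (unthinned 3.33% and 54.2%).

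The genes of largest ratio included Slc2a3, Uncx and Ndrg1. The glucose transporters Slc2a3 and Slc2a1 were 62.7-fold (58.1 to 67.8) and 14.5-fold (14.01 to 14.9) higher, Ndrg1 203-fold (162 to 257), Ddit4 15.5-fold (14.9 to 16.0) and Ankrd37 16.6-fold (15.5 to 17.7). The heat shock genes Hspa1a and Hspa1b were 199-fold (153 to 266) and 74.3-fold (60.9 to 91.5) higher, the neural adhesion molecule Ncam1 19.8-fold (18.7 to 20.9) and Ptges 33.9-fold (30.2 to 38.2). The homeobox gene Uncx (ENSMUSG00000029546, chromosome 5, 139543494 to 139548179) was at 282 CPM against 2 UMIs in ICR E10.5, a ratio of 10161 (2812 to 83911). Ndrg1, Hspa1a, Hspa1b, Ddit4, Uncx and Slc2a1 lead cluster 2, which is the NICD class, and Hes5, Ptges and Ncam1 lead clusters of unnamed NICD cells. In NICD macrophage-like cells Ankrd37 was at 219 CPM against 228 in otic epithelium-like cells, Hspa1b at 92.1 against 103 and Slc2a3 at 359 against 581. Of 11 measured hypoxia and glycolysis genes all were at least 2-fold higher (median 2.45, percentile 100), among them Bnip3 (8.41-fold) and Pfkp (42.0-fold).

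Lower in NICD were also the adhesion molecule Cntn5 (26.3-fold, 24.6 to 28.0) and the potassium channel Kcnq3 (28.3-fold, 25.6 to 31.2), which, like Tbx1, lead clusters of ICR cells, and Ube2s (18.3-fold, 17.2 to 19.4). Nme2 (43.0-fold), Aarsd1 (91.2-fold), Cpne1 (188-fold), Cox16 (21.3-fold) and Pabpn1 (11.05-fold) completed the 10 lowest, and each of these 5 shares exons on its own strand with a feature that the NICD annotation alone holds. Without genes of that kind the next were Lhfp (15.04-fold), Cadm2 (11.2-fold), Tpm3-rs7 (44.2-fold), Dpp10 (62.8-fold) and Grik2 (7.88-fold), chosen after the data were seen. Ube2s was also among the 10 lowest in neural tube-like (33.9-fold), pharyngeal endoderm-like (23.9-fold) and all cells (23.2-fold), as was Nme2 in each. An effect of annotation on Ube2s stays open, although no shared exon was found for it.

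**Figure D4:**
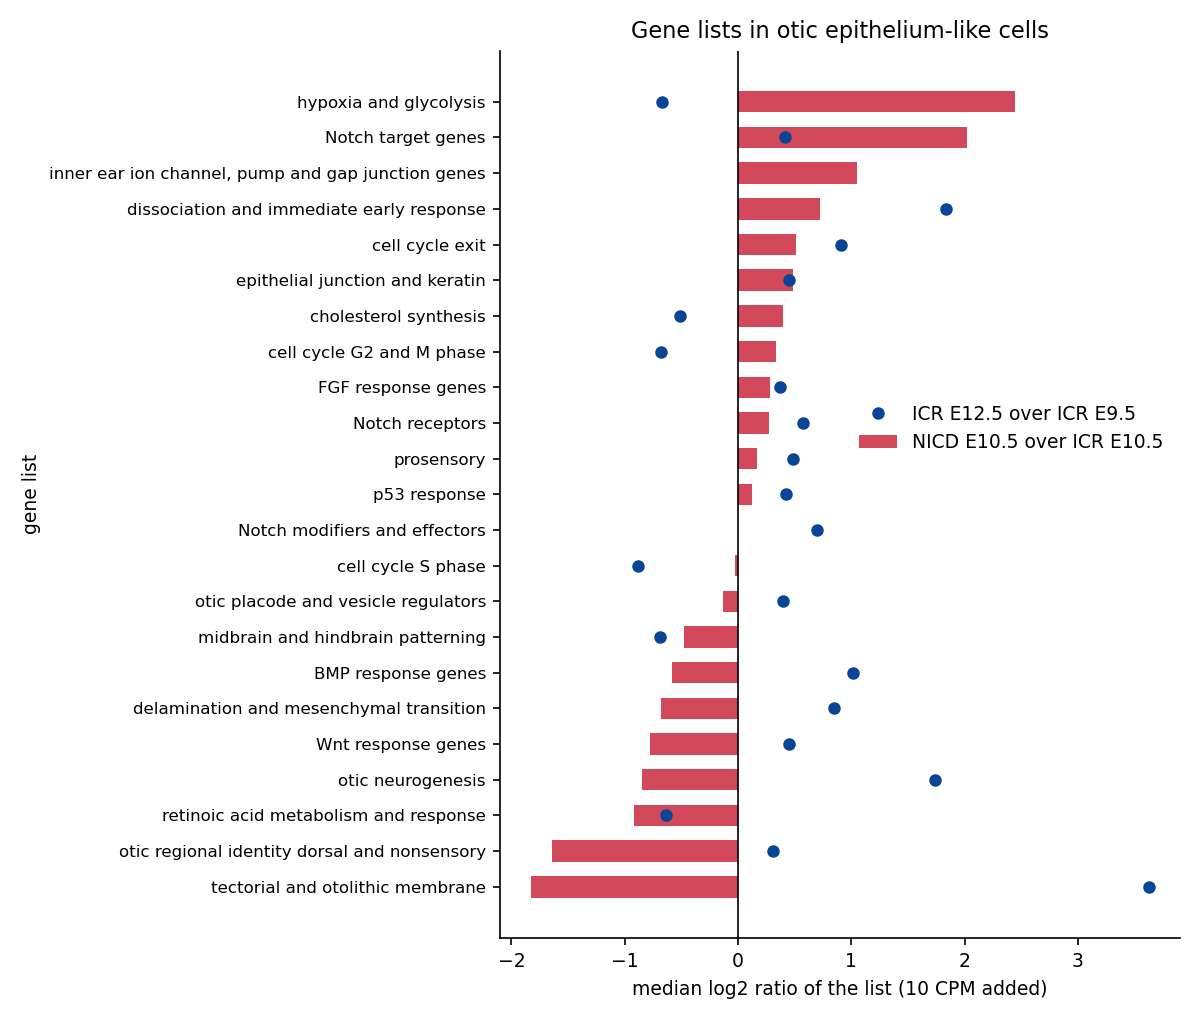
Median log2 ratio of each gene list with at least 3 measured members in otic epithelium-like cells, with 10 CPM added, as bars for NICD over ICR at E10.5 and as dots for ICR E12.5 over E9.5. The Notch target list lies at 2.02 in NICD and 0.42 over stage, and the tectorial and otolithic membrane list at −1.82 and 3.63.

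Regional identity genes of the dorsal and nonsensory otocyst were lower in 9 of 10 (median −1.64, percentile 0): beside Oc90 and Tbx1, Bmp4 was 8.74-fold, Lmx1a 4.11-fold and Dlx5 3.80-fold lower. With a minimum of 2000 UMIs 4 of 10 were lower and 1 higher. Placode and vesicle regulators were near level as a list (−0.14, percentile 23.3; 3 lower and 1 higher of 15). Gata2 was 13.9-fold, Eya4 3.84-fold and Gata3 3.22-fold lower and Pax8 3.28-fold higher, while Pax2, one of the markers, was at a ratio of 0.655 and Hmx3 at 0.986. Prosensory genes had a median of 0.16 (percentile 96.5; 3 higher, 2 lower of 12), with Isl1 4.64-fold lower and Sox2 at 1.32. Medians were −0.85 for otic neurogenesis genes (percentile 0.37; 1 lower of 4), −0.57 for the 2 measured neuronal differentiation genes (Tubb3 3.57-fold lower), −1.82 for tectorial and otolithic membrane genes (percentile 0.16; 2 lower of 3) and −0.91 for retinoic acid genes (percentile 0.12; 1 lower of 3). Free RNA from neuroblast-like cells, 11.2% of ICR E10.5 and 0.03% of NICD, was not tested for the lower neuronal genes. Wnt response genes were lower in 3 of 7 (−0.78, percentile 0.03), with Lef1 9.52-fold and Dkk1 9.37-fold lower, and BMP response genes in 3 of 9 (−0.58, percentile 0.11), with Msx2 5.06-fold and Bambi 3.01-fold lower. FGF response genes had a median of 0.29 (percentile 97.7), with Spry1 3.61-fold and Spry2 2.37-fold higher. Some medians turned: with a minimum of 2000 UMIs they were 0.02 for BMP response, 0.01 for retinoic acid and 0.15 for placode genes, and with no minimum CPM −0.01 for prosensory genes. Others came near 0, at −0.04 for otic neurogenesis and −0.11 for tectorial and otolithic membrane genes with no minimum CPM. Against ICR E9.5 they were 0.26 for BMP response, 0.59 for otic neurogenesis and 0.08 for placode genes, and against ICR E11.5 −0.15 for FGF response.

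Epithelial keratins were higher, Krt19 4.72-fold, Krt8 3.56-fold and Krt18 3.51-fold (list median 0.49, percentile 99.96; 3 higher of 13), and delamination genes had a median of −0.68 (percentile 0.34). The Hox gene Hoxb2 was 12.6-fold higher (11.1 to 14.4), and midbrain and hindbrain genes were lower in 2 of 4 (−0.48, percentile 1.86), with Irx3 6.87-fold lower, but their median was 0.64 with each library clustered alone, 0.00 with no minimum CPM and 1.28 against ICR E11.5. Immediate early genes had a median of 0.73 (percentile 99.99; −0.07 against ICR E11.5), cholesterol synthesis genes 0.40 (percentile 99.7; −0.09 with a minimum of 2000 UMIs), p53 response genes 0.12 (percentile 83.8; −0.03 against ICR E11.5) and ion channel genes 1.05 (percentile 96.8, 3 measured), while Espn, the only hair cell gene measured, was 2.16-fold and the Hedgehog target Ptch1 1.2-fold higher. In the cell cycle, the S phase list stood at −0.03 (percentile 51.8), the G2/M list at 0.34 (percentile 99.97) and exit genes at 0.52 (percentile 99.9), with Cdkn1a 2.58-fold lower and Cdkn1b 2.18-fold higher. The share of cells with at least 5 G2/M UMIs was 76.1% (74.7 to 77.4) in NICD and 60.7% in ICR E10.5 (87.2% and 77.6% unthinned), and 8.54% of the NICD cells had 4 or 5. Strain, cross, annotation and library differ together with the transgene here. How many NICD cells were named otic depended on the setting: 3100 with each library clustered alone, 1204 with a minimum of 2000 UMIs and 8 with doublets kept.

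The neural tube-like class, cluster 29 in both, held 71 NICD and 117 ICR E10.5 cells. Otic neurogenesis and neuronal differentiation genes were lower in NICD, and G2/M and BMP response genes were higher. Genes of cell type and region, among them Ttr, Otx2, Lmx1a and Hox genes, also differed between the 2 sets of cells. The folds here may therefore mix composition and region with level. Otic neurogenesis genes, shared with central neurons, were lower in 14 of 15 (median −1.76, percentile 0) and neuronal differentiation genes in 12 of 13 (−2.26, percentile 0): Stmn2 was 9.87-fold (8.03 to 12.2), Elavl3 8.41-fold (5.93 to 12.3), Tubb3 6.32-fold (5.54 to 7.23) and Isl1 11.3-fold (6.91 to 19.6) lower, and Neurod1, with 1 UMI, had a ratio of 156 (27.8 to 6191). Neurod1 stood at 192 CPM in the ICR E10.5 cells of this class and at 191 over all ICR E10.5 cells. Free RNA from neuroblast-like cells was not tested for these lower genes. The G2/M list was higher in 16 of 22 (1.195, percentile 100). Ttr, a choroid plexus gene that leads this cluster, had 479 UMIs in NICD and 0 in ICR E10.5. Higher by ratio were Rspo1 (57.0-fold, 24.0 to 177), Rspo3 (55.5-fold, 21.2 to 206) and Lmx1a (23.9-fold, 11.8 to 56.6) of the roof plate, the BMP target Bambi (41.8-fold, 19.9 to 105), Ldb2 (63.1-fold, 26.6 to 196), Otx2 of the fore- and midbrain (91.9, 24.9 to 767, from 2 UMIs), Colec12 (183, 62.2 to 893, from 3 UMIs) and Metrnl (53.1, 17.7 to 262, from 3 UMIs).

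BMP response genes were higher there in 7 of 9 (1.36, percentile 100), with Msx1 6.22-fold (4.49 to 8.79) and Id2 3.71-fold (3.19 to 4.34) higher, and Wnt1 was 11.4-fold higher (6.06 to 23.8). Hox genes were lower in 4 of 7 (−1.72, percentile 0), with Hoxb3 3.85-fold lower (2.72 to 5.58) and Hoxb4 at 0 UMIs in NICD and 48.2 CPM in ICR. Of the Notch targets (2 higher of 4, median 0.62, percentile 97.1), Hes1 was 10.9-fold (6.33 to 20.2) and Hey1 3.01-fold (1.86 to 4.97) higher, while Hes5 (0.989, 0.834 to 1.17) and Nrarp (0.766, 0.538 to 1.08) did not differ beyond counting error. With background subtracted that median was 0.20. Hypoxia and glycolysis genes were higher in 10 of 11 (1.62, percentile 100). Kcnmb2 was 83.2-fold (28.2 to 405, 3 UMIs in NICD) and Ube2s 33.9-fold (19.2 to 65.9) lower; the other 7 of the 10 lowest besides Neurod1 were Nme2, Cox16, Pik3r3, Fam89b, Cpne1, Aarsd1 and Rnasek, which share exons with a feature of the NICD annotation alone. These sums rest on 812524 and 1244024 UMIs.

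Pharyngeal endoderm-like cells, 157 in NICD and 632 in ICR E10.5, had Notch targets, Hspa1a and Hspa1b higher in NICD. The class was held by different clusters, cluster 31 in NICD (135 cells) and clusters 6 (516) and 24 (116) in ICR. For clusters 6 and 24 this was the class of second highest score. All 6 measured Notch targets were at least 2-fold higher (median 2.17, percentile 100): Hes5 was 274-fold (156 to 532), Hes1 6.39-fold (5.79 to 7.05), Hey1 6.15-fold (5.42 to 6.99) and Nrarp 5.25-fold (4.25 to 6.51) higher, and the ligand Jag1 3.56-fold (3.19 to 3.98). Hes1 also reached 402 CPM in this class at ICR E12.5, against 524 in NICD. Hspa1a and Hspa1b were 177-fold (114 to 291) and 171-fold (101 to 314) higher, the matrix gene Ecm1 181-fold (82.1 to 497), the calcium channel subunit Cacna2d1 11.47-fold (10.6 to 12.4), Ptges 33.9-fold (27.7 to 41.8), Sfrp2 22.5-fold (19.3 to 26.3), Tmem100 28.5-fold (18.9 to 44.6) and Slc2a3 10.9-fold (9.33 to 12.8), and Uncx had 185 UMIs in NICD and 0 in ICR E10.5. Hes5, Hspa1a, Hspa1b, Ecm1 and Cacna2d1 lead cluster 31.

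Lower in NICD pharyngeal endoderm-like cells were the adhesion molecule Kirrel3 (45.9-fold, 23.2 to 107), the transcription factor Ebf1 (38.0-fold, 19.96 to 83.3; nearly level, at a log2 of 0.08, with a minimum of 2000 UMIs) and Ube2s (23.9-fold, 17.9 to 32.7). The other 7 of the 10 lowest, Nme2, Adnp, Igf2, Tomm6, Cpne1, Znrd2 and Cox16, share exons with a feature of the NICD annotation alone. Neuronal differentiation genes were lower in 3 of 5 (−1.84, percentile 0), with the neurofilament Nefm 19.5-fold lower, and retinoic acid genes in 4 of 5 (−1.11, percentile 0.04), with the degrading enzyme Cyp26a1 14.9-fold and Crabp1 4.60-fold lower. Nefm leads the epibranchial neuroblast cluster 16, which held 5.02% of ICR E10.5 and 0.073% of NICD cells. Free RNA from such cells was not tested for the genes lower in NICD. Cholesterol synthesis genes were higher in 6 of 11 (1.07, percentile 100), hypoxia and glycolysis genes in 4 of 10 (0.89, percentile 100) and G2/M genes in 4 of 22 (0.60, percentile 100), with Cdk1 2.69-fold higher. These sums rest on 2171314 and 7623269 UMIs, and with each library clustered alone no NICD cell had this name at a score of 1 and 437 had it at a score of 0.8. The neuronal differentiation median was −0.12 at Leiden resolution 0.5 and −0.34 with a minimum of 2000 UMIs.

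Over all cells, with no class names involved, 6 of 9 measured otic neurogenesis genes (median −1.81) and 6 of 9 neuronal differentiation genes (median −1.86) were lower in NICD, at percentile 0 for both. Neurod1 was 146-fold (127 to 167), Insm1 109-fold (87.7 to 138) and Neurog1, which starts otic neurogenesis, 109-fold (79.6 to 154) lower in NICD, with Dcx 23.1-fold, Elavl3 19.8-fold and Tubb3 16.8-fold lower. The neuronal differentiation gene Stmn2, which leads cluster 5, was 2.95-fold higher (2.88 to 3.02). Zeb1, a delamination factor, was 21.2-fold lower (19.7 to 22.9), and it, Neurod1 and Insm1 lead the neuroblast cluster. The Notch targets had a median of 2.59 (percentile 100, 4 of 4 higher): Hes5 was 39.5-fold (36.3 to 43.0), Hey1 8.80-fold, Hes1 6.06-fold and Nrarp 2.35-fold higher, and Jag1 6.02-fold. Every large cluster of NICD cells shared this: Hes1 stood at 211, 351, 200 and 200 CPM in clusters 0, 2, 5 and 10, Hey1 at 363, 302, 347 and 339 and Jag1 at 317, 362, 232 and 327. Pax8 was 6.97-fold higher and Sox10 3.90-fold lower, and these folds mix composition with level.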

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

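The feature EGFP is counted only in the NICD library and is outside the genes shared by the libraries, so it stood in no comparison. It was listed because it gave 4099 UMIs in the cells of that library, above the limit of 3. These UMIs are 24.8 CPM (24.1 to 25.6), against 17.7 CPM in empty droplets from 121 UMIs and 11.7 CPM (5.33 to 22.1) in macrophage-like cells. An EGFP UMI was found in 22.5% of all cells (21.8 to 23.1; median 9857 UMIs per cell) and in 12.2% of macrophage-like cells (4.63 to 24.8; median 12373). No library without the transgene counts this feature, and no explanation was tested.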

How the results depend on the processing

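Of the 1897 values of named genes under alternatives, 1541 stayed within counting error, 355 moved and 1 reversed. Of the 1371 list medians, 801 stayed, 532 moved and 38 reversed. The cells per library stayed within 1.5 times the count in all 20 values, and of 110 shares of otic epithelium-like and neuroblast-like cells 44 moved beyond counting error. The Notch target median in NICD otic epithelium-like cells lay between 1.36 and 2.67, that of E12.5 over E9.5 between −0.01 and 0.66, that of NICD neural tube-like cells between 0.20 and 0.76, that of NICD pharyngeal endoderm-like cells between 1.63 and 2.47, the tectorial median between 1.30 and 5.21, and the neuronal differentiation median in neuroblast-like cells between −2.49 and −0.51. No paired analysis was possible because each group is 1 library and the results come from no test. Depth limits genes under 50 CPM and small classes such as the 71 and 117 neural tube-like cells. No value could be given for NICD otic epithelium-like cells with doublets kept (8 cells), for neural tube-like cells with at most 5% mitochondrial UMIs (35 in NICD), for that class with each library clustered alone (0 cells), or for NICD pharyngeal endoderm-like cells in that setting (0 cells) and with Notch and cell cycle genes among the variable genes (32 cells). Below are all values that reversed and, for the leading results only, the values that moved, and the cause was not tested. Settings called added were chosen after seeing the data.

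With each library clustered alone, neuroblast-like shares were 14.82% at E9.5, 10.47% at E10.5 and 0.11% in NICD. In stage ratios the tectorial median was 3.69 in otic epithelium-like cells, and in neuroblast-like cells Notch ligands were −0.46, neuronal differentiation −2.49, BMP response −0.24 and G2/M 0.36. In NICD otic epithelium-like cells, Notch targets were 2.19 and midbrain and hindbrain genes 0.64. A naming score of at least 0.8 on top of this (added) gave the same list medians and ICR shares, but NICD shares of 9.66% for neuroblast-like, 12.03% for mesenchyme-like and 2.90% for pharyngeal endoderm-like cells. The minimum of 1 was set after the names at 0.8 had been seen, but a score of 0.8 with the joint clustering (added) leaves 4 of 15064 NICD cells neuroblast-like, so the 9.66% needs both choices. Otic epithelium-like shares moved as well, among them to 70.1% at E10.5 with clusters named irrespective of their mitochondrial share (added) and to 81.6% at E12.5 with at most 5% mitochondrial UMIs.

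With a minimum of 2000 UMIs, the E10.5 neuroblast-like share was 10.16%, the stage medians of Notch targets and tectorial genes 0.06 and 3.75, and in NICD Notch targets were 1.82, placode regulators 0.15, BMP response 0.02, retinoic acid 0.01 and cholesterol synthesis −0.09. In NICD pharyngeal endoderm-like cells Notch targets were 2.43 and Ebf1 0.08 with that minimum, and Notch targets 2.39 with doublets kept, 2.02 with cells thinned, 2.47 with a prior of 1 CPM and 1.63 with no minimum CPM. With at most 5% mitochondrial UMIs, the E10.5 neuroblast-like share was 8.95%, stage Notch targets 0.59, and in neuroblast-like cells Notch ligands −0.33 and neuronal differentiation −0.70. With doublets kept, the E10.5 and E11.5 shares were 9.99% and 8.36%, stage Notch targets 0.09, and in neuroblast-like cells neuronal differentiation −0.62 and BMP response −0.13. At Leiden resolution 0.5 the E10.5 share was 9.39%, stage Notch targets 0.59 and neuroblast Notch ligands −0.18. With Notch and cell cycle genes among the variable genes the share was 8.93% and neuroblast Notch ligands −0.19. Leaving out barcodes under 0.5% mitochondrial UMIs (added) gave neuroblast Notch ligands of −0.21 and NICD placode regulators of 0.02. With cluster 14 counted as otic (added) stage Notch targets were 0.59, and without genes sharing exons across annotations (added) neuroblast neuronal differentiation was −0.68.

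For stage Notch targets and tectorial genes, median-of-ratios scaling gave 0.21 and 3.49 and a prior of 1 CPM 0.66 and 5.21. The tectorial median was 3.73 as a mean over cells and 2.67 with cells thinned. NICD Notch targets were 1.94 with cells thinned and 2.67 with that prior. With background subtracted, neural tube Notch targets were 0.20. With no minimum CPM, stage medians in otic epithelium-like cells were 0.07 for Notch targets, −0.04 for otic neurogenesis, 0.00 for Wnt response, 0.35 for retinoic acid and 1.57 for tectorial genes, neuronal differentiation in neuroblast-like cells was −0.51, and in NICD Notch targets were 1.36, prosensory genes −0.01 and midbrain and hindbrain genes 0.00.

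For E11.5 over E10.5 the otic medians were −0.01 for Notch targets, −0.35 for regional identity, −0.05 for prosensory genes, −0.25 for Wnt response, −0.05 for BMP response, 1.30 for tectorial genes and 0.00 for G2/M. For E12.5 over E10.5 they were 0.48 for Notch targets, −0.05 for regional identity, −0.15 for Wnt response and 1.62 for tectorial genes. Against ICR E9.5, NICD Notch targets were 2.07, placode regulators 0.08, otic neurogenesis 0.59 and BMP response 0.26. Against ICR E11.5, Notch targets were 1.84, FGF response −0.15, midbrain and hindbrain genes 1.28, immediate early genes −0.07 and p53 response −0.03. The G2/M shares (ICR by stage, then NICD) were 98.8%, 77.6%, 66%, 40.1% and 87.2% without thinning, 96.8%, 71.9%, 61.6%, 37.9% and 85.3% at 3 UMIs, and 68.3%, 44.0%, 40.4%, 25.1% and 54.8% at 10 UMIs.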

Other observations

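Several genes that differ between stages stood in NICD otic epithelium-like cells near their E9.5 level. Eya4 was at 75.8, 302 and 626 CPM at ICR E9.5, E10.5 and E12.5 and at 78.6 in NICD. Gata2 was at 3.46, 33.1 and 78.1 CPM and at 2.39 in NICD, Otx2 at 0.372, 12.51 and 60.2 and at 0.175, and Pax8, lower with stage, at 49.3, 11.47 and 0.48 and at 37.6. Ldha was at 1691, 755 and 487 CPM and at 1671 in NICD. Others lay elsewhere: Oc90 was at 3.79 CPM in NICD, below the 37.8 of E9.5, and Lin28a at 15.3, near the 18.2 of E10.5 and far from the 74.2 of E9.5. Among the genes of largest stage ratio, Prtg, Sall4, Trim71, Car4, Sparc, Nfia, Nfib and Clu stood nearest their E10.5 CPM in NICD. Crabp1, Rasl11a, Mylk and Car14 stood nearest their E11.5 CPM. Ntm, Il1rapl1, Frmpd4 and Lum stood nearest their E9.5 CPM, and Mt1, at 136 CPM, lay above its 60.9 at E9.5. All genes in this paragraph were picked after their values were seen, and no tally over all stage genes was made.

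Cluster 32, left unnamed, was led by the hair cell factors Pou4f3 and Atoh1 and by Myo6, and held 62 of the E12.5 cells (0.541%). In it Atoh1 stood at 525 CPM (471 to 583), Sox2 at 555 (499 to 615) and the Notch ligand Dll1 at 98.3 (75.8 to 125), while Hey2 had 0 UMIs. Cluster 14, also unnamed, had Hey1 at 185 CPM (178 to 192), Hey2 at 90.0 and Jag1 at 154 at E12.5. Cluster 26, led by Dlk1, Six6, Pitx1 and the pituitary hormone subunit Cga, held 467 E12.5 cells (4.08%). In cluster 17 Jag1 was at 217 CPM at E10.5 and 114 at E12.5, and Sox2 at 369 and 314.

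Of the tests below, those of shared exons, of surface ectoderm-like cells and of free RNA as the whole of the E12.5 difference were chosen after seeing the result, and the other tests before.

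Notch target genes were higher in the NICD library in otic epithelium-like cells, which the transgene in the design would give. A hypoxia state of these cells is argued against: in the 961 cells with the lowest hypoxia and glycolysis share, the Notch target median was 2.06, although hypoxia genes in those cells still had a median of 1.04. Free RNA is argued against, since macrophage-like cells held these genes at 9.5% of the otic level, although the level in empty droplets had a median of 87.9% of it. Mouse strain, litter or library preparation in place of the transgene stays open, because 0 libraries could serve as a strain control.

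Genes lower in the NICD library in otic epithelium-like cells could follow from the transgene or from the annotation. Of the measured genes that share exons on their strand with a feature of 1 annotation, 25.3% were lower and below the ICR range, against 1.6% of the others, as that explanation predicts for these genes. As the whole cause it is argued against, since 26.7% of the lower genes share such exons in GENCODE M21. That release holds 296 of the 364 features of the NICD annotation alone, so some shared exons may have been missed. Intronic reads counted differently stay open: over all cells, where the test was set, the longest 20% of genes lay 0.63 above the shortest 20% in log2, opposite in sign to fewer intronic reads in NICD. In otic epithelium-like cells the medians were close, −0.036 and −0.154, but 67 of the longest 20% and 30 of the shortest 20% were 2-fold lower in NICD.

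Genes higher at E12.5 in otic epithelium-like cells could be development, the stage being the design, or come from free RNA or gene length. Macrophage-like cells of that library held these genes at a median of 74.3% of the otic level, which passed the limit set for free RNA. Empty droplets, however, held them at a median of 61.9%, below the macrophage level. This test therefore cannot tell free RNA from another source. In surface ectoderm-like cells the median was 42.4%, which decides nothing. Free RNA as the whole of the difference is argued against, since the level in empty droplets reached the otic level for 11.7% of these genes. A trend with gene length stays open: 57.7% of the genes stayed at least 2-fold higher once the median of their length bin was subtracted, and the longest 20% of genes had a median of 0.73 against −0.29 for the shortest 20%.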
